A study of Mus musculus with 6 samples.

How the data were processed

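Total RNA of mouse kidneys was extracted with TRIzol and spin columns, made into stranded mRNA libraries and sequenced as single 75 bp reads, per the labels' protocols. There were 6 libraries, 3 IVCC and 3 Sham, grouped and numbered by their titles. The values used are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), as deposited by the authors in 1 table of 24346 gene symbols with 1 column per library. TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and the mm10 build are listed in the submitters' processing notes, without their roles. The annotation, filters and any scaling between libraries are not given in the sources used here. The deposited FPKM sum to between 719896 and 1118258 per library, and each library's median ratio to the geometric mean library lies between 0.982 and 1.02. The gene Kap alone takes 11.0% to 16.6% of each sum.

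FPKM carry no read totals, so depth was estimated from the steps between values. For genes with transcripts of 1500 to 5000 bp and values below 0.1 FPKM, 79.9% to 84.0% of values per library were whole multiples of 1 read within a tolerance of 0.1, under an assumed fragment length of 200 bp. The resulting library sizes are nominal, and whole reads were not recovered well enough for a count test. An FPKM of 0 can be a failed estimate, and 8197 to 8738 symbols per library were listed at 0. Of the genes tested, 85 are small RNA genes, whose FPKM from an mRNA library depend on an effective length near the length of the gene.

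Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12090 genes; 12256 fell below). FPKM were transformed to log2(FPKM + 1), so that fold changes are on that scale and understate the change of low genes. The 2 groups were compared two-sided with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so none was used for single genes. Of 36 gene lists, the 32 with at least 5 members tested were compared with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was run with the mean-variance trend (trend.var), which the design had not specified. This setting was chosen after results without it had been seen (8 lists higher, 2 lower). Counts "adjusted over the list alone" adjust limma's p over the members of 1 list. Lists share some members, such as Icam1 and Thbd, and are not independent.

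Apart from camera's trend, the gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 higher and 10 lower genes past the threshold with the largest folds and no overlap. Since none passed, it took the 5 per direction with the smallest p, without predicted genes and small RNA genes. It added the 3 members with the smallest adjusted p of each called list, and Havcr1, Lcn2, Vcam1, Ren1, Acta2, Col1a1, Pdgfrb, Vegfa, Slc34a1 and Hbb-bs. Of the genes this rule takes, 2 are not reported here. The other settings tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, 3 scalings (TPM, median ratio and quantile), and eBayes without the trend and robust. They also included the replicate number as a block, each library left out in turn, a minimum log2 fold change of 1, and for lists an estimated correlation, fry and ranks. Added after the data had been seen were a correction for transcript length and GC content, that correction with the block, and leaving out the libraries numbered 3 of both groups. The correction subtracted, per library, a natural-spline fit of each gene's deviation from its mean on log2 transcript length and GC content. Length was the median over GENCODE M21 basic transcripts, chosen over the median of all transcripts because it tracked the library deviations more closely, and 96.3% of tested genes had a value. Coordinates are from the same annotation of GRCm38, the assembly that mm10 names.

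Both tests were tested on simulated data for the 12090 genes, with gene variances drawn from the fitted prior; an earlier version with more uniform variances was replaced after its result was seen, because it flattered the test. Of 100 genes changed by a log2 fold of 1, limma recovered 65.0%, and of 100 changed by a log2 fold of 2 it recovered 95.4%, with a mean of 8.8 false calls per run over 10 runs. These runs drew noise independently for each gene and changed all 200 genes at once, which eases the adjusted threshold. The recovery is therefore not the power of the gene test in the real data. Over 100 runs with independent noise camera called a list shifted by 0.4 in all 100 and a mean of 0.05 false lists. With the real residual correlation between genes and no group effect, it called a mean of 6.61 lists per run (1 to 15), and 0 with an estimated correlation. Recovery of a shifted list was simulated only at the preset correlation, so 0 calls at an estimated one do not show that no list differs. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.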

Results

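RNA was sequenced from kidneys of C57BL/6 mice in 2 groups of 3 libraries each, one group after the operation that the labels call IVCC and the other after sham surgery. The series concerns renal congestion, and the comparison of the 2 groups asks how the kidney transcriptome differs after IVCC surgery. The labels do not spell out IVCC and do not say that the replicates were separate animals, so p-values measure the spread between these libraries. Depth is not given by FPKM values, but the steps between the lowest values gave nominal library sizes of 8240000 to 9190000 reads in IVCC and 6140000 to 7210000 in Sham. Each nominal size in IVCC was above each one in Sham, and true depth was not measured. The Spearman correlation over genes was 0.971 to 0.976 between libraries of the same group and 0.968 to 0.977 between libraries of different groups.

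Ren1, which encodes renin, the enzyme that starts the angiotensin cascade, averaged 105.5 ± 9.93 FPKM in IVCC and 57.9 ± 1.89 FPKM in Sham (SD, n = 3 each). Gene lists of stroma, capillaries, podocytes, macrophages and the interferon response were called higher in IVCC, and those of oxidative phosphorylation and heat shock lower, by camera at a preset correlation of 0.01 between genes. With a correlation estimated per list camera called 0 lists (smallest adjusted p = 0.257), and fry's directional test called 0. The interferon-induced chemokines Cxcl9 and Cxcl10 passed only when adjusted over their list alone. Markers of tubular injury were not called in either direction. No single gene was called: limma gave 0 of 12090 tested genes at an adjusted p under 0.05, with a smallest adjusted p of 0.790. At an unadjusted p under 0.05 there were 431 genes, 205 higher and 226 lower in IVCC, where chance alone gives about 604 on average. Genes vary together, so this count is unstable, and other splits of the 6 libraries into 3 and 3 gave 66 to 3370. It was 214 without IVCC replicate 1, 1039 without IVCC replicate 3, and 2388 with the replicate number as a block. The 3 IVCC values lay all above or all below the 3 Sham values for 8.3% of genes, against 10% by chance.

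The 5 higher genes with the smallest unadjusted p were Ren1, Fbln5, Lyz2, Cxcl10 and Prelp, none of which passed the adjustment over all genes. Ren1 (chromosome 1, 133350510 to 133360325, plus strand, GRCm38) had a log2 fold change of 0.85 with a standard error of 0.11 in limma, at an adjusted p of 0.790. Fbln5, an elastic fibre protein, averaged 20.0 ± 0.542 FPKM in IVCC and 12.7 ± 1.33 FPKM in Sham. Prelp, a leucine-rich matrix proteoglycan, averaged 6.53 ± 0.235 and 3.84 ± 0.555 FPKM. Lyz2, the lysozyme of myeloid cells, averaged 22.8 ± 3.84 and 13.3 ± 0.332 FPKM. Cxcl10, a chemokine that draws T cells, averaged 8.34 ± 2.80 and 2.70 ± 0.788 FPKM, a log2 fold change of 1.32 with a standard error of 0.24. The 5 lower genes were Ceacam2, Cyp51, Slc22a13, Ppih and Akr1c18, with limma adjusted p-values from 0.790 to 0.905. Cyp51 (chromosome 5, 4081145 to 4104746, minus strand), a demethylase of sterol synthesis, averaged 44.5 ± 1.80 FPKM in IVCC and 74.1 ± 5.45 FPKM in Sham. Slc22a13, an organic anion transporter, averaged 23.4 ± 4.25 and 45.1 ± 6.02 FPKM. The steroid-reducing enzyme gene Akr1c18 averaged 7.01 ± 2.88 and 21.5 ± 6.00 FPKM, with a log2 fold change of -1.51 and a standard error of 0.28. This was the largest fold of these 10 genes on the log2(FPKM + 1) scale, which understates that of the lower Cxcl10. Ceacam2 averaged 1.93 ± 0.529 and 5.76 ± 1.01 FPKM, and Ppih, a cyclophilin of the spliceosome, 16.1 ± 0.832 and 25.5 ± 2.41 FPKM.

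**Figure D1:**
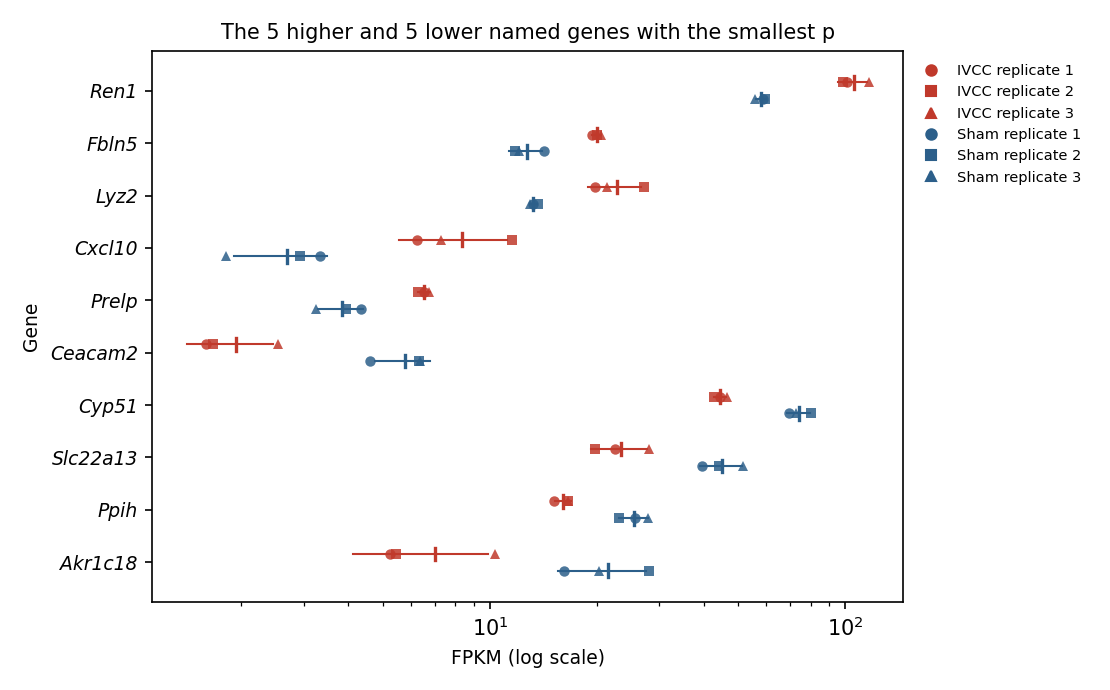
FPKM per library, on a log axis, of the 5 higher and 5 lower named genes with the smallest unadjusted p; red symbols are IVCC, blue symbols are Sham, the tick is the group mean and the bar is 1 SD either side (n = 3). The groups do not overlap for any of the 10 genes, and Ren1 runs from 98.6 to 116.8 FPKM in IVCC against 55.7 to 59.3 FPKM in Sham.

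The fibroblast and extracellular matrix list had the smallest camera p of the 32 lists tested. Of its 30 tested members 29 had a higher fitted value in IVCC, 16 of them with no overlap between the groups. The median log2 fold change was 0.36 (camera adjusted p = 2.261e-16 with a preset correlation of 0.01, adjusted p = 0.257 with an estimated correlation). None of its members passed the adjustment over all genes, and 0 passed when adjusted over the list alone. Ctgf, a matricellular growth factor, averaged 36.8 ± 7.16 FPKM in IVCC and 22.5 ± 0.836 FPKM in Sham. Among the fibrillar collagen genes, Col3a1 averaged 6.71 ± 0.188 and 4.58 ± 0.521 FPKM. Col1a2 averaged 7.90 ± 1.12 and 5.22 ± 0.603 FPKM, and Col1a1 2.95 ± 0.0646 and 1.74 ± 0.425 FPKM. The pericyte, smooth muscle and mesangial list was not called (11 members higher and 7 lower, camera adjusted p = 0.422), except as higher with a filter at 5 FPKM (adjusted p = 0.0204), and its members went both ways. Pdgfrb, a receptor of pericytes, averaged 6.33 ± 0.440 FPKM in IVCC and 4.14 ± 1.22 FPKM in Sham, whereas the contractile gene Acta2 averaged 13.8 ± 6.06 and 18.8 ± 3.95 FPKM. Ren1 belongs to this list and passed when adjusted over the list alone (adjusted p = 0.001706, limma).

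Podocyte transcripts were higher in IVCC for 16 of 17 tested members, with a median log2 fold change of 0.47 (camera adjusted p = 1.445e-10, adjusted p = 0.257 with an estimated correlation). Synpo, an actin-binding protein of foot processes, averaged 8.91 ± 2.05 FPKM in IVCC and 5.03 ± 0.486 FPKM in Sham. The transcription factor gene Tcf21 averaged 10.9 ± 1.26 and 7.67 ± 1.23 FPKM. Blood endothelial transcripts were higher for 24 of 28 members, with a median log2 fold change of 0.21 (camera adjusted p = 6.682e-08, adjusted p = 0.257 with an estimated correlation). Igfbp3 averaged 104.3 ± 9.72 FPKM in IVCC and 68.5 ± 9.71 FPKM in Sham. The junction protein gene Pecam1 averaged 15.6 ± 0.287 and 11.8 ± 0.993 FPKM, and the apelin receptor gene Aplnr 3.13 ± 0.203 and 2.09 ± 0.291 FPKM. The endothelial activation list was called at the edge of the threshold (14 of 17 members higher, camera adjusted p = 0.0495, adjusted p = 0.257 with an estimated correlation). It was not called without camera's variance trend (adjusted p = 0.0504) or after the length and GC correction (adjusted p = 0.0514). Its leading members were the adhesion genes Icam1, at 7.90 ± 0.681 and 6.16 ± 0.989 FPKM, and Vcam1, at 2.17 ± 0.297 and 1.66 ± 0.648 FPKM, with the thrombomodulin gene Thbd at 4.42 ± 0.406 and 3.68 ± 0.399 FPKM. The lymphatic endothelial list, with only 6 members tested, was higher for 5 of them (camera adjusted p = 0.0211, adjusted p = 0.272 with an estimated correlation). Its mean log2 shift was 0.21, and 0.14 without IVCC replicate 3 or 0.10 without Sham replicate 2. Its leading members were Nrp2, at 2.004 ± 0.381 and 1.19 ± 0.347 FPKM, and the lymphangiogenic ligand genes Figf and Vegfc.

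Macrophage and dendritic cell transcripts were higher in IVCC for 19 of 20 members, with a median log2 fold change of 0.40 (camera adjusted p = 1.871e-11, adjusted p = 0.257 with an estimated correlation). Lyz2 passed when adjusted over the list alone (adjusted p = 0.0158, limma), but not without any 1 of the Sham libraries (adjusted p = 0.0538 to 0.0852). The pore-forming protein gene Mpeg1 averaged 5.14 ± 1.45 FPKM in IVCC and 2.86 ± 0.536 FPKM in Sham, and the class II antigen presentation gene H2-Ab1 88.0 ± 12.4 and 64.2 ± 5.67 FPKM. The interferon response list was higher for 31 of 33 members, with a median log2 fold change of 0.24 (camera adjusted p = 8.027e-09, adjusted p = 0.513 with an estimated correlation). Its mean log2 shift was 0.30, and 0.15 without IVCC replicate 2 or 0.20 without Sham replicate 3. Igtp, an interferon-induced GTPase, averaged 21.9 ± 6.14 and 11.8 ± 3.09 FPKM. The related gene Irgm1 averaged 37.1 ± 9.71 and 25.2 ± 1.90 FPKM, and the transcription factor gene Irf1 11.3 ± 2.12 and 7.60 ± 1.59 FPKM. The list of inflammatory cytokines and NF-kB targets was higher for 15 of 18 members, with a median log2 fold change of 0.15 (camera adjusted p = 0.0001847, adjusted p = 0.257 with an estimated correlation). Its unadjusted limma p was under 0.05 for 3 members. The list was not called without the libraries numbered 3 of both groups (camera adjusted p = 0.106). Cxcl9 averaged 2.80 ± 0.466 FPKM in IVCC and 0.905 ± 0.476 FPKM in Sham. Both Cxcl9 and Cxcl10 passed when adjusted over the list alone (adjusted p = 0.0132 each, limma), Cxcl9 not without IVCC replicate 2 (adjusted p = 0.0577). The complement and coagulation list was higher for 18 of 25 members (camera adjusted p = 0.0434, adjusted p = 0.257 with an estimated correlation). Its mean log2 shift was 0.06, and 0.03 without Sham replicate 1 or 0.09 without Sham replicate 3. The plasminogen activator gene Plat averaged 14.8 ± 2.79 and 9.02 ± 0.619 FPKM. Its member Serpina1a went the other way, at 7.78 ± 5.23 FPKM in IVCC and 20.9 ± 9.23 FPKM in Sham. It belongs to a family of near-identical copies, so its value is uncertain. Neutrophil and lymphocyte lists had only 3 and 2 members tested and were not put to the list test.

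The oxidative phosphorylation list was lower in IVCC for 30 of 32 members, with a median log2 fold change of -0.22 (camera adjusted p = 0.0003019, adjusted p = 0.778 with an estimated correlation). After the length and GC correction the median was -0.10 (camera adjusted p = 0.00528), and after quantile normalization it was -0.02 and the list was not called (adjusted p = 0.713). The mean log2 shift of -0.19 was -0.04 without Sham replicate 3 and -0.10 without IVCC replicate 2, and -0.30 without IVCC replicate 3 or Sham replicate 2. The camera adjusted p at the preset correlation was 8.081e-10 with the replicate number as a block and 0.0003993 without both libraries numbered 3. Relative to gene means over the 6 libraries, the list lay at -0.14, -0.28 and 0.12 in IVCC replicates 1 to 3. In the Sham libraries of the same numbers the list lay higher, at 0.02, -0.13 and 0.40. The groups overlapped for every one of its members. The ATP synthase gene Atp5f1 averaged 508.6 ± 42.4 FPKM in IVCC and 601.2 ± 85.1 FPKM in Sham. The complex I genes Ndufv2 and Ndufb5 averaged 201.4 ± 25.4 and 307.9 ± 52.8 FPKM in IVCC against 242 ± 54.3 and 374.3 ± 88.4 FPKM in Sham. Heat shock transcripts were lower for 14 of 18 members, with a median log2 fold change of -0.09 (camera adjusted p = 0.0341, adjusted p = 0.257 with an estimated correlation). Their mean log2 shift was -0.14, and -0.09 without IVCC replicate 2. The small chaperone gene Cryab averaged 68.6 ± 25.0 FPKM in IVCC and 139 ± 22.6 FPKM in Sham. Its log2 fold change was -1.05, and it was the only member with an unadjusted limma p under 0.05. Hspe1 averaged 420.8 ± 56.2 and 536.8 ± 93.9 FPKM, and Stip1 54.8 ± 3.50 and 62.3 ± 1.43 FPKM. Immediate early genes were higher for 15 of 17 members (camera adjusted p = 0.0495, adjusted p = 0.538 with an estimated correlation), and were not called without camera's variance trend (adjusted p = 0.0504). Their mean log2 shift was 0.15, and 0.23 without IVCC replicate 2 or Sham replicate 1. Rhob averaged 19.9 ± 3.37 and 16.1 ± 2.2 FPKM, Btg2 6.31 ± 1.20 and 5.11 ± 0.582 FPKM, and Ier2 7.95 ± 1.497 and 6.36 ± 1.44 FPKM.

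**Figure D2:**
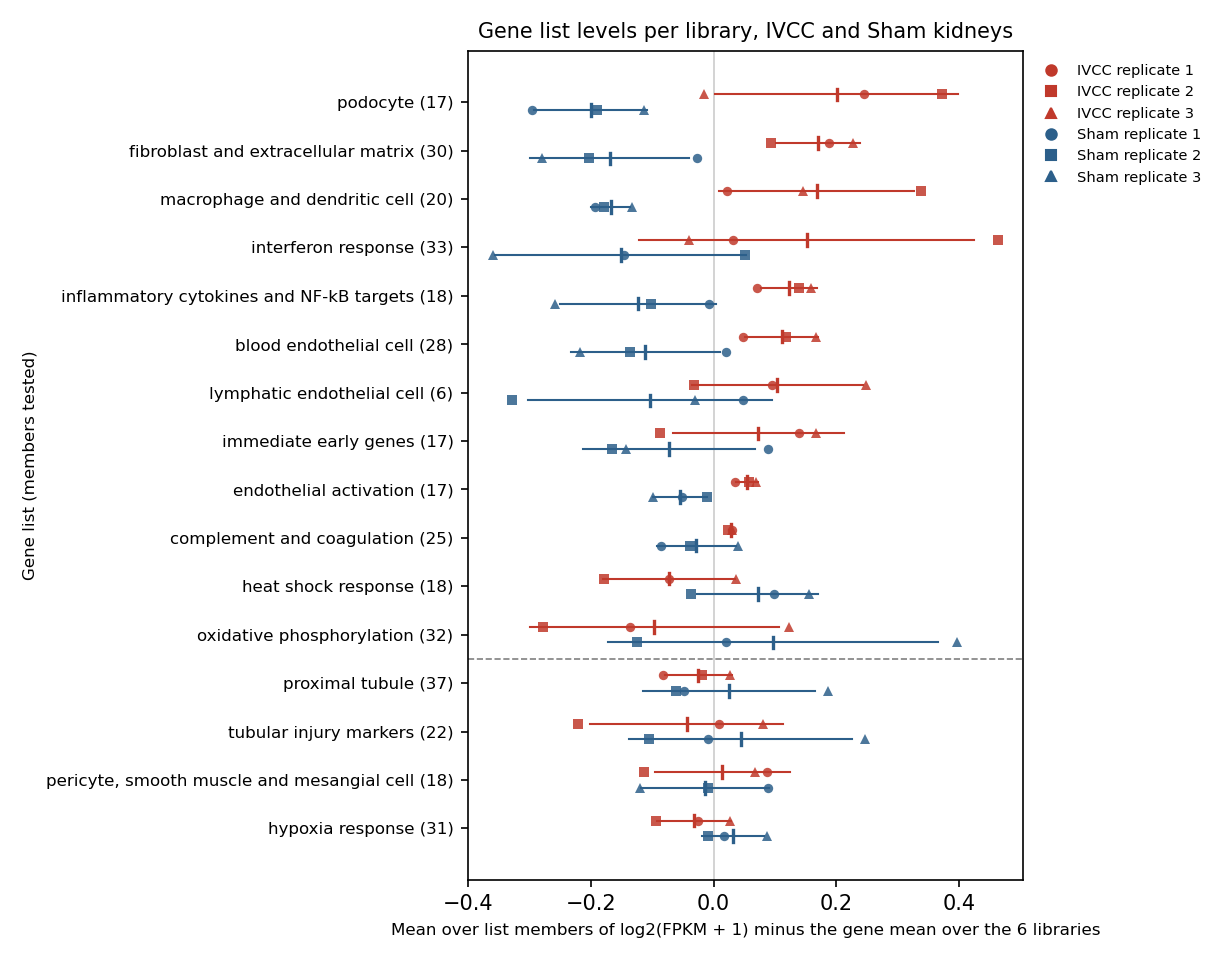
Level of each of the 12 called gene lists (above the dashed line) and of 4 lists that were not called, as the mean over members of log2(FPKM + 1) minus each gene's mean over the 6 libraries; red symbols are IVCC, blue symbols are Sham, the tick is the group mean and the bar is 1 SD either side (n = 3). The fibroblast list lies between 0.09 and 0.23 in IVCC and between -0.28 and -0.03 in Sham. The groups overlap for the lymphatic, interferon, heat shock, immediate early, oxidative phosphorylation and complement lists, and for the 4 lists not called.

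Tubular injury markers were not called (9 members higher and 13 lower, camera adjusted p = 0.711). Lcn2, which encodes the injury marker NGAL, averaged 1.56 ± 1.35 FPKM in IVCC and 2.2 ± 0.983 FPKM in Sham. Havcr1, which encodes KIM-1, stayed below the filter at 0.612 ± 0.417 and 0.563 ± 0.192 FPKM. Proximal tubule transcripts were split, 15 higher and 22 lower (adjusted p = 0.683), but were called higher after quantile normalization (adjusted p = 0.00564). The phosphate transporter gene Slc34a1 averaged 2465 ± 101.5 and 2184 ± 66.2 FPKM. The lists of the thick ascending and thin limbs (7 higher, 12 lower), the distal convoluted and connecting tubule (13 higher, 4 lower), principal cells (8 higher, 7 lower) and intercalated cells (12 higher, 6 lower) were not called either. Under other settings the distal list was called higher without IVCC replicate 3 (adjusted p = 0.0297), Sham replicate 1 (0.00188) or the libraries numbered 3 (0.0108) and on ranks (0.0467). The limb list was called lower without Sham replicate 2 (adjusted p = 0.00411) and the intercalated list higher without IVCC replicate 2 (adjusted p = 0.0405). The hypoxia list was not called (10 higher, 21 lower, adjusted p = 0.219), and its member Vegfa averaged 85.0 ± 3.77 and 82.1 ± 25.2 FPKM. The list of renin, angiotensin, aldosterone and sodium handling genes had 15 members higher and 6 lower and was not called (adjusted p = 0.102), except as higher after quantile normalization (adjusted p = 0.00867) and with the replicate block (adjusted p = 0.0270). Ren1 passed when adjusted over that list alone (adjusted p = 0.00199, limma).

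Among the stress and metabolic lists, NRF2 targets had 6 members higher and 21 lower, fatty acid oxidation 6 higher and 26 lower, and endoplasmic reticulum stress 11 higher and 13 lower. The remaining counts were cell cycle 8 higher and 14 lower, p53 targets 12 higher and 10 lower, osmotic response 7 higher and 6 lower, and glucocorticoid response 10 higher and 7 lower. None of these 7 lists was called by camera, nor were the circadian clock list (10 higher, 7 lower) and the list of androgen-dependent and sex-linked genes (6 higher, 9 lower). Under other settings fatty acid oxidation was called lower with the replicate block (adjusted p = 0.0157), with the block plus the length and GC correction (0.0126), and without IVCC replicate 3 (0.0343), Sham replicate 1 (0.0230) or Sham replicate 2 (0.0499). NRF2 targets were called lower with the block (adjusted p = 0.0164) and without Sham replicate 2 (0.0462), and the androgen list without IVCC replicate 2 (0.0397) or Sham replicate 1 (0.0292). Adipose markers, which would show perirenal fat, had 1 member higher and 4 lower. The desaturase gene Scd1 passed when adjusted over that list alone, with a log2 fold change of -0.67 (adjusted p = 0.005871, limma). Urothelial and adrenal markers had only 2 and 4 members tested. Of the urothelial ones Psca passed when adjusted over the list alone, with a log2 fold change of -1.16 (adjusted p = 0.0499, limma), but its groups overlapped. It did not pass without IVCC replicate 1 or 2 or Sham replicate 1 or 3 (adjusted p = 0.126 to 0.163). The mean log2 shift of the urothelial list was -0.98, and -0.44 without Sham replicate 3 or -1.52 without Sham replicate 2. With no filter on low values the list was called lower (camera adjusted p = 0.0284). The erythroid list had 4 members higher and 4 lower. Its member Hbb-bs was listed at 15.8, 0.008 and 0.008 FPKM in IVCC and at 18.3, 0.007 and 20.98 FPKM in Sham. It shares reads with near-identical globin genes, so these values are uncertain.

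All 12 list calls were made at the preset correlation of 0.01 and none with an estimated one, and simulated data with the real residual correlation and no group effect gave a mean of 6.61 called lists. The calls of the endothelial activation, lymphatic, heat shock, immediate early, oxidative phosphorylation and complement lists were each lost after quantile normalization and without at least 1 single library, such as oxidative phosphorylation without Sham replicate 3 (adjusted p = 0.292).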

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

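With limma no named gene passed the threshold under any setting, and all named genes kept their direction except Vegfa. Its log2 fold change was 0.10, against -0.13 without the libraries numbered 3, and -0.15 to 0.30 without single libraries, the lowest without Sham replicate 3; the cause was not tested. The main counts were 0 genes higher and 0 lower, and 10 lists higher and 2 lower. Lists called higher fell to 6 on the TPM scale (1 lower), which moved the median log2 fold change of all genes to 0.15. Lists called lower came to 1 with a filter at 5 FPKM and 0 after quantile normalization (8 higher, the proximal tubule and renin lists among them). Of the 20 lists tested and not called, 9 were called under at least 1 other setting. Camera with an estimated correlation and fry each called 0 higher and 0 lower, and the cause was not tested. The estimated correlation was at or below 0.01 for 3 of the 12 called lists (endothelial activation, complement and heat shock), which lost their calls too. A larger correlation within these 3 lists therefore cannot be why they lost them. The p-values given at the preset and at an estimated correlation thus do not differ by the correlation alone. How often camera recovers a shifted list at an estimated correlation was not simulated. Fry's test for change in either direction, read after seeing the data, called the pericyte, renin and fibroblast lists (adjusted p = 0.0023, 0.0075 and 0.0353). The pericyte and renin lists share Ren1, the gene with the smallest p of all, so their calls are not separate findings. Robust eBayes has no list equivalent and was not run for lists. Leaving out single libraries gave 0 to 3 genes higher, 0 to 1 lower, 7 to 11 lists higher and 1 to 5 lower. The genes so called were Mir762 and Snora43 without IVCC replicate 1, Snora65, Mir1957b and Snord7 without IVCC replicate 2, Snora17, Mir215, Snora23 and Mir678 without IVCC replicate 3, and Mir1892 without Sham replicate 2, all of them small RNA genes. Lists called lower were 5 without Sham replicate 2 and 1 without Sham replicate 3. After seeing the data, leaving out the libraries numbered 3 was added (3 genes higher and 1 lower, the small RNA genes called without IVCC replicate 3; 6 lists higher, 2 lower), as was the length and GC correction (0 genes; 9 lists higher, 2 lower).

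The replicate numbers do not pair the samples by the rule set in advance, which asked for a correlation over 0.1 in each same-numbered pair. The deviations of same-numbered libraries correlated at -0.11, 0.34 and 0.32 for numbers 1, 2 and 3, so only number 1 failed. IVCC replicate 1 correlated little with the other Sham libraries too, at 0.07 with replicate 2 and 0.02 with replicate 3. Still, of the 6 ways to match IVCC with Sham libraries, the labelled one had the highest mean correlation over all genes (0.186, next 0.152). The replicate block gave 0 genes higher and 0 lower (smallest adjusted p 0.0775, with 2388 genes at an unadjusted p under 0.05), 9 lists higher and 4 lower. With the block camera also called the NRF2, fatty acid oxidation and renin lists (adjusted p = 0.0164, 0.0157 and 0.0270), while the lymphatic and complement lists were not called (0.0773 each). With the length and GC correction the block gave 1 gene lower, the small RNA gene Snord22, 8 lists higher and 3 lower.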

Other observations

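Gene groups and tests in these paragraphs were chosen after values had been seen, except the counts of called lists and of smallest p over other splits, whose tests were written first. Genes known to be induced by interferon gamma were higher in IVCC for 17 of 17 tested members, 9 of them without overlap between groups, with a median log2 fold change of 0.50 (camera p = 4.442e-17, p = 0.037 with an estimated correlation, both unadjusted). Iigp1 averaged 10.3 ± 4.01 FPKM in IVCC and 4.94 ± 2.90 FPKM in Sham, and the invariant chain gene Cd74 183.3 ± 29.6 and 134.7 ± 6.78 FPKM. Genes known mainly as type I interferon targets had a median log2 fold change of 0.20, with 13 of 14 members higher (camera p = 0.003608, p = 0.314 with an estimated correlation). Isg15 averaged 7.95 ± 2.16 and 6.17 ± 1.08 FPKM, Oasl2 3.38 ± 0.425 and 2.62 ± 0.165 FPKM, and Ifit3 6.51 ± 1.13 and 6.53 ± 1.82 FPKM. The difference between these groups was not tested, and they share members with the interferon list. The interferon gamma group also holds Cd74, H2-Aa, H2-Ab1 and H2-Eb1 of the macrophage list and Cxcl9 and Cxcl10 of the cytokine list, so it is no separate evidence.

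Of 19 tested transporter genes of the Slc22 family, 16 were lower in IVCC and 4 without overlap (median log2 fold change -0.12, camera p = 0.0001842, p = 0.1003 with an estimated correlation). Besides Slc22a13, Slc22a19 averaged 35.9 ± 5.43 FPKM in IVCC and 75.0 ± 20.9 FPKM in Sham, and Slc22a7 80.0 ± 16.5 and 148.7 ± 29.5 FPKM, while the abundant Slc22a6 averaged 428 ± 53.6 and 459.4 ± 109 FPKM. Of 23 sterol synthesis and uptake genes, 17 were lower (median log2 fold change -0.13, camera p = 0.001568, p = 0.0706 with an estimated correlation). Cyp51 stood far from the rest: Hmgcs1 averaged 228.9 ± 20.6 and 238 ± 29.0 FPKM, and Sqle 28.7 ± 0.848 and 33.0 ± 4.29 FPKM.

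The 12 called lists form the first pattern to weigh. A transcript length gradient is present, since log2 fold changes correlated with length over genes (Spearman's rho 0.501). Deviations of single libraries correlated with length at 0.381, 0.599 and -0.427 in IVCC replicates 1 to 3. In Sham replicates 1 to 3 they correlated with it at -0.106, 0.308 and -0.59. IVCC replicate 3 and Sham replicate 2 thus went against a gradient between the groups. After the length and GC correction 11 of the 12 lists were still called in the same direction at the preset correlation. This argues against the gradient as the whole cause of those calls, within the limits of that preset. With an estimated correlation the fibroblast, podocyte and macrophage lists had an adjusted p of 0.318 each after the correction (camera). The fibroblast median went from 0.36 to 0.27, the macrophage median from 0.40 to 0.50, and the oxidative phosphorylation median from -0.22 to -0.10. A lower share of tubular RNA stays open: the fibroblast list shifted by 0.31 more than the pericyte list (log2, standard error 0.04), but pericyte members went from -0.70 to 0.85 around a median of 0.06 (SD 0.38), too wide to decide. Correlation between genes of a list above the preset value, estimated for 9 of the 12, stays open and fits the number of calls: 15 of 100 simulated runs without a group effect called at least 12 lists, although 0 of them gave a smallest adjusted p as small. The 10 splits of the 6 libraries are too few to give a share under 0.05; 2 splits, the real one included, called at least 12 lists (highest other 13), and for single genes a real count of 0 leaves nothing to compare (highest other 3). Other splits also gave single lists a small adjusted p (camera, preset correlation). The interferon list reached 1.404e-11 with IVCC replicate 1 and Sham replicates 1 and 3 as a group, against 8.027e-09 in the real split. The blood endothelial list reached 1.349e-11 with IVCC replicate 1 and Sham replicates 2 and 3, against 6.682e-08. No other split went below the real 2.261e-16 of the fibroblast list, which reached 1.113e-12 in another split.

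Ren1 is the second pattern. Its log2 fold change was 0.85 (standard error 0.11) before and 0.95 (0.11) after the length and GC correction, which argues against the gradient as its cause. A larger glomerular share, which would carry renin-producing cells along, may account for part of it: Ren1 shifted by 0.45 more than the podocyte list, with a 95% interval from -0.11 to 1.01, so the explanation cannot be told apart from a change within those cells. Within IVCC, Ren1 was highest in replicate 3 (116.8 FPKM), where the podocyte list was lowest (-0.02 relative to gene means). It was lowest in replicate 2 (98.6 FPKM), where that list was highest (0.37). Within Sham, replicate 3 had the lowest Ren1 (55.7 FPKM) and the highest podocyte level (-0.11). With 3 libraries per group these orders do not decide the question. The 10 splits are too few to give a share under 0.05; in 4 of them, the real one included, some gene had a p as small as that of Ren1 (9.476e-05, against 3.065e-13 for Snora68, 2.636e-07 for Mir29c and 3.444e-09 for Hbb-bs). Without predicted and small RNA genes, the smallest p was below that of Ren1 in 2 of the other splits, with Ugt1a6b at 7.399e-05 and Hbb-bs.

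Clock genes are the third pattern: Per1 was at 9.32 and 8.54 FPKM in the libraries numbered 3 of IVCC and Sham, 6.13 and 6.38 in those numbered 2, and 3.53 and 3.58 in those numbered 1, and Arntl was at 1.66 and 1.61 in those numbered 3 against 3.43 to 4.63 in the other 4. Of 17 clock genes 10 had both libraries numbered 3 on one side of the rest (highest other pair 7), against 41.9% of all genes (binomial p = 0.122), while for number 1 it was 7 of 17 against 8.5% (p = 0.000289) and for number 2 it was 2 of 17 against 31.1% (p = 0.985). The length gradient stays open: after correction 7 of the 10 kept this and 3 others gained it, so 10 of 17 were apart against 29.6% of all genes (p = 0.0114), with 8 of 17 against 11.9% for number 1 (p = 0.000351) and 0 of 17 for number 2, but the binomial p takes co-regulated genes as independent. Over clock genes the deviations of same-numbered libraries correlated at a mean of 0.78, the highest of the 6 ways to match IVCC with Sham libraries (highest other 0.50), and at 0.92, 0.52 and 0.92 for numbers 1, 2 and 3. A candidate explanation is that libraries of the same number were taken at a similar time of day; no label gives the time, and genes are not independent replicates.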
